A study of Homo sapiens with 12 samples.

How the data were processed

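RNA from MCF10A, a non-tumorigenic human mammary epithelial line, and MCF7, an estrogen receptor positive breast cancer line, was measured on 12 Affymetrix exon arrays. Each line had 3 arrays of cells transfected with a control siRNA (siCTRL) and 3 arrays of cells transfected with an siRNA against a region shared by DDX5 and DDX17 (siDDX5-17). Per the labels, the replicates were biological, the siRNA was used at 26.6 nM, and cells were collected after 48 h. A single siRNA was used for both genes, so effects of its sequence on other transcripts cannot be separated from effects of the knockdown.

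The deposited values are log2 RMA values (robust multi-array average: background correction, normalization and probe summary). A probe set roughly stands for 1 exon. The submitters' processing notes name Affymetrix Power Tools, RMA and the hg18 genome build. Versions, background settings and detection filters were not given in the sources used here. The file held 1411399 probe sets with 0 missing values. The array medians lay between 5.723 and 5.7806 in MCF10A and between 6.1722 and 6.2157 in MCF7. Arrays of a line shared nearly the same distribution and differed from those of the other line, as if each line had been normalized on its own. No pair of arrays was identical.

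Probe sets were named from the platform annotation. A gene symbol was given alone for 357604 probe sets, several symbols were given for 15322, and no symbol was given for 1038473; the last 2 kinds entered no gene value. Symbols were brought to current names with the RefSeq gene annotation for the GRCh38 assembly, which was used for names alone. Of 19560 symbols, 16472 were current, 2966 were updated and 122 were kept as given, which left 19488 genes. Exon positions were not used here, so probe sets are given by their identifiers.

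A probe set was kept if its mean over all 12 arrays was at least 5.96, the median of that mean over the whole file; 74.6% of the probe sets with 1 symbol passed. A gene value was the median polish (at most 20 iterations) over at least 4 kept probe sets, and 15734 genes were tested. The splicing index was the probe set value minus the gene value on the same array. It was tested in genes with at least 5 kept probe sets, where the probe set and the gene both reached the brightness minimum in the line compared. Array number, with 3 per group, limits the precision.

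Both steps were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend), with 1 mean per group over all 12 arrays, 8 residual degrees of freedom and, for genes, 6.5 prior degrees of freedom. The contrasts were siDDX5-17 minus siCTRL in each line, the difference between these effects (MCF7 minus MCF10A), and siCTRL of MCF7 minus siCTRL of MCF10A. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes or probe sets of a comparison and a threshold of 0.05. Overlaps between the lines were compared with Fisher's exact test, and correlations were taken. Both run across genes or probe sets, which are not independent replicates. The 38 gene lists were tested against the other genes with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated per list. The rotation test fry was run as an alternative. Some lists share members, so their calls are not independent of each other. Other tools were the data.table package in version 1.17.8, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

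The gene lists, the comparisons, the tests, the thresholds, the alternatives and the rule for naming genes were fixed before the data were examined, except where the text says that a choice was made later. The rule named DDX5 and DDX17, the 10 largest rises and the 10 largest falls of each knockdown comparison and of the control comparison without overlap between the groups, and up to 3 members with the smallest adjusted p of each list in each knockdown comparison. It also named the 6 largest positive and the 6 largest negative differences between the lines, and up to 5 luminal and 5 basal markers in the control comparison. For probe sets it named the 6 largest splicing index differences per line, at most 1 per gene, and up to 8 genes of a list of 50 known splicing events. Members of a list outside the 3 with the smallest adjusted p, and genes or probe sets singled out as shared by both lines, were chosen after their values were seen.

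Replicate numbers were checked for pairing in the data. After the group means were removed, MCF7 arrays of the same replicate number correlated across genes at 0.626, 0.344 and 0.503, each its array's highest correlation with the other group; in MCF10A the same values were -0.0212, 0.0146 and -0.0222. A fit with the replicate number within each line as a block was therefore read as a paired fit in MCF7.

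The procedure was tested on simulated data made from the mean of each line and replicate spreads like those of the arrays, with 50 changed genes at each fold. In MCF10A, 10% of the genes with a 1.25-fold change were recovered, 50% at 1.5-fold, and 100% at 2-fold and 4-fold. In MCF7 the shares were 6%, 66%, 98% and 100%. For probe sets, MCF10A gave 0% of 45 at 1.5-fold, 38.6% of 44 at 2-fold and 100% of 37 at 4-fold, and MCF7 gave 6% of 50, 36.2% of 47 and 100% of 45. False calls made up 0% of the gene calls and 6.9% of the probe set calls in MCF10A, but 23.3% and 51.1% in MCF7, whose replicates spread more than the spread pooled over 12 arrays. With only the 6 arrays of a line in the fit, they made up 4.7% and 2.33% in MCF10A and 5.43% and 2.5% in MCF7. Of the unchanged MCF7 features, 0.264% of the genes and 0.0289% of the probe sets were called with 12 arrays. With 6 arrays these were 0.0451% and 0.000407%. The share of false calls depends on how many features change. Fewer were changed here than were called on the real arrays, and no pairing was simulated, so these shares need not hold for the real calls. A list shifted by 1.5-fold was called in both lines, with 0 of the other lists. The simulated genes varied independently of each other, so this says nothing about false list calls where the genes of a list vary together.

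The alternatives left out each array in turn, blocked on the replicate number, fitted only the arrays compared, quantile normalized the values or centred each array on its median, removed or raised the brightness minimum, took the gene value as a mean or a plain median, used eBayes with trend and robust options, asked for a 1.5-fold change, replaced the splicing index by limma's diffSplice, and kept only genes changed under 1.5-fold. A brightness minimum per line and a fit without both first MCF7 arrays were chosen after seeing the data.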

Results

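Gene and exon expression was measured on 12 exon arrays, 3 in each of 4 groups: MCF10A with siCTRL, MCF10A with siDDX5-17, MCF7 with siCTRL and MCF7 with siDDX5-17. The siRNA targeted DDX5 and DDX17, paralogous DEAD-box RNA helicases that act in transcription, splicing and microRNA processing. The design asks which genes and exons depend on the 2 helicases in a non-tumorigenic and in a tumor line, and whether the lines differ. The first principal component, with 85.9% of the variance over genes, separated the lines, and the second, with 9.3%, separated the MCF10A siRNA groups. The components were taken on the values as deposited, so the first also holds the median shift of 0.911 between the control arrays of the lines. On the fourth, with 1.3%, the 2 first MCF7 replicates scored 0.559 and 0.58, apart from the other arrays. The median SD of a gene between replicates was 0.0859 (MCF10A siCTRL), 0.0964 (MCF10A siDDX5-17), 0.136 (MCF7 siCTRL) and 0.132 (MCF7 siDDX5-17) on the log2 scale.

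Both targeted transcripts fell in both lines. In MCF10A, DDX5 was at 10.596, 10.671 and 10.564 on the siCTRL arrays (mean 10.61, SD 0.055, n = 3) and at 8.807, 9.017 and 9.137 on the siDDX5-17 arrays (mean 8.99, SD 0.17, n = 3), a log2 change of -1.62 (SE 0.098, adjusted p = 3.88e-09) that left 32.5% of the control level. In MCF7, DDX5 was at 12.185, 12.283 and 12.302 with siCTRL (mean 12.26, SD 0.062) and at 10.823, 10.902 and 11.051 with siDDX5-17 (mean 10.93, SD 0.12), a change of -1.33 (SE 0.098, adjusted p = 8.1e-07) that left 39.7%. DDX17 in MCF10A was at 10.667, 10.458 and 10.501 with siCTRL (mean 10.54, SD 0.11) and at 8.9, 8.945 and 8.983 with siDDX5-17 (mean 8.94, SD 0.042), a change of -1.60 (SE 0.096, adjusted p = 3.66e-09) that left 33%. In MCF7 it was at 10.93, 10.674 and 10.914 (mean 10.84, SD 0.14) and at 9.156, 9.245 and 9.348 (mean 9.25, SD 0.097), a change of -1.59 (SE 0.096, adjusted p = 2.06e-07) that left 33.2%. The difference between the lines was not past the threshold for DDX5 (0.29, SE 0.14, adjusted p = 0.111) or DDX17 (0.01, adjusted p = 0.96). For DDX5 it was past it, at 0.36, when the gene value was taken as a mean. The fall ran along both transcripts. In all, 28 of 29 DDX5 probe sets were lower in MCF10A and 27 in MCF7, as were 34 and 35 of the 35 DDX17 probe sets.

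**Figure D1:**
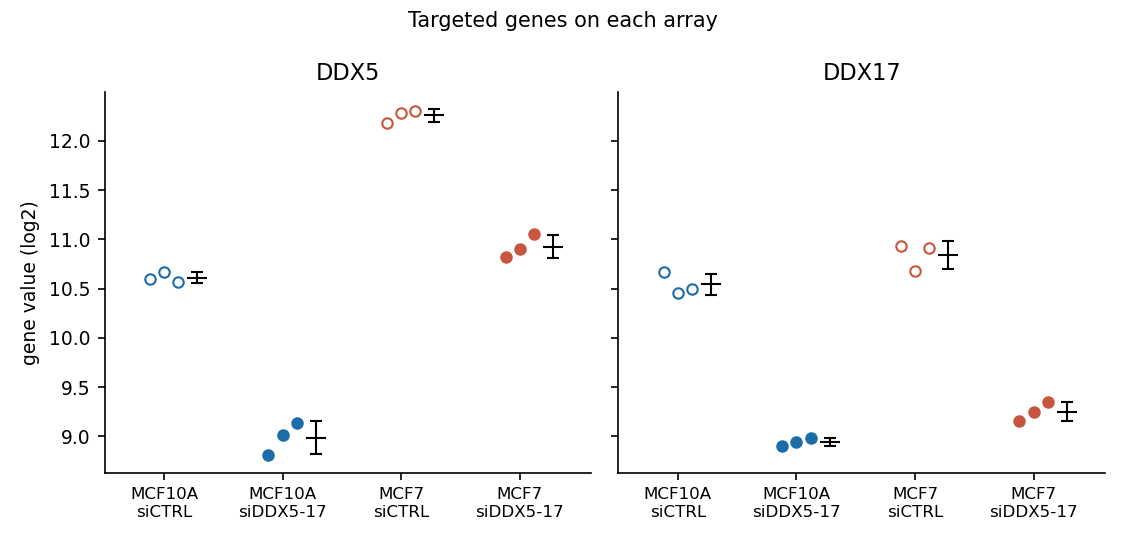
Gene values (log2) of DDX5 and DDX17 on each of the 12 arrays, by cell line and siRNA, with 1 point per array. All siDDX5-17 arrays lie below all siCTRL arrays of the same line for both genes.

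In MCF10A, most measured G2/M genes (39 of 40) and basal markers (14 of 20) fell with the knockdown, and most stress response genes (21 of 30) rose. KRT15, a keratin of basal epithelial cells, fell by 4.92 on the log2 scale (SE 0.10, adjusted p = 3.2e-13), and TOP2A, the topoisomerase that resolves chromosomes before mitosis, fell by 4.74 (SE 0.17, adjusted p = 1.99e-11). The kinetochore gene CENPF changed by -4.18 (SE 0.092, adjusted p = 3.66e-13), the proliferation marker MKI67 by -4.12 (SE 0.096, adjusted p = 6.05e-13) and CCNB1, the mitotic cyclin B, by -3.98 (SE 0.14). The largest rises were CRYAB, a small heat shock protein, at 4.97 (SE 0.17, adjusted p = 1.31e-11), ARG2, a mitochondrial arginase, at 3.12 (SE 0.093, adjusted p = 4.02e-12), FCRL6 at 2.99 (SE 0.10, adjusted p = 1.62e-11) and OLAH at 2.96 (SE 0.12). The other genes of largest change were DEPP1 (2.69), GLIPR1 (2.67), RDH10 (2.50), CFAP161 (2.30), AVIL (2.26) and MORN4 (2.26) among the rises, and PCDHB14 (-4.29), ASPM (-4.09), KIF18A (-3.98), NUF2 (-3.89) and DTL (-3.89) among the falls. PCDHB14 has near-identical paralogs, which makes its value uncertain. For every gene given by name as changed by the knockdown, all 3 siDDX5-17 arrays lay on the same side of all 3 siCTRL arrays of the line. The list counts below also hold genes whose groups overlap. Among named genes and list members past the threshold, these were 2 of 654 in MCF10A and 14 of 274 in MCF7.

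Across 15734 genes, 3161 were higher and 4882 lower in MCF10A (51.1% of the genes tested), of which 766 and 2964 changed at least 1.5-fold, 222 and 1402 at least 2-fold, and 23 and 242 at least 4-fold. The groups did not overlap in 10518 genes (66.8%, where chance gives 10%). The balance of directions depended on the scaling between arrays: 39.3% of the called genes were higher as deposited, 59.8% after quantile normalization (6021 higher, 4047 lower) and 59.6% after median centring (5924 and 4017). These scalings moved the median change of all genes from 0.0192 to 0.147 and 0.156. The medians of the called lists below kept their sign under both.

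Genes of cell division fell nearly as a whole in MCF10A. Of 40 measured G2/M and mitosis genes, 39 fell and 0 rose, the same counts adjusted over the list alone, with a median of -2.76 (adjusted p = 3.54e-24, and adjusted p = 0.0713 with an estimated correlation). The exception was the centromere histone CENPA at 0.16 (adjusted p = 0.257). Of 47 DNA replication and G1/S genes, 42 fell and 0 rose (42 and 0 adjusted over the list alone), with a median of -0.81 (adjusted p = 3.52e-11, and adjusted p = 0.0713 with an estimated correlation). They included the clamp loader RFC3 (-2.32) and thymidylate synthase TYMS (-1.98). The 5 members not past the threshold were CDT1, POLD1, E2F1, E2F2 and SLBP. All 5 measured replication-dependent histones, of 48 listed, fell (5 adjusted over the list alone), with a median of -0.65 (adjusted p = 0.0307, and adjusted p = 0.3 with an estimated correlation). These were H2AC6 (-1.59), H2AC20 (-0.84), H2BC11 (-0.52), H1-2 and H1-4. With a plain median H2AC20 was at -1.72 and H2BC11 at -0.79.

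Basal markers and cholesterol synthesis genes fell as well. Of 20 basal and myoepithelial markers, 14 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.94 (adjusted p = 0.00022, and adjusted p = 0.0881 with an estimated correlation). They included TP63, the master transcription factor of basal epithelium, at -2.86, and P-cadherin, CDH3, at -2.40, whereas the ectonucleotidase NT5E rose by 2.13. KRT14, KRT6B, KRT17, EGFR and COL17A1 were not past the threshold. Of 20 cholesterol synthesis genes, 18 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -0.998 (adjusted p = 1.11e-06, and adjusted p = 0.0713 with an estimated correlation). STARD4 (-2.04), lanosterol synthase LSS (-1.82) and ACAT2 (-1.72) fell, PMVK rose by 0.45, and SC5D was not past the threshold.

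Genes of the unfolded protein and integrated stress response rose in MCF10A. Of 30, 21 rose and 6 fell (21 and 6 adjusted over the list alone), with a median of 0.65 (adjusted p = 7.63e-05, and adjusted p = 0.0713 with an estimated correlation). The transcriptional regulators NUPR1 (2.23) and ATF3 (1.45) rose. The fallers PDIA4 (-1.56), PDIA6, EDEM1, HSP90B1, CRELD2 and SEL1L act in protein folding and degradation in the endoplasmic reticulum. Immediate early and MAPK feedback genes had 14 higher and 3 lower of 32 (14 and 3 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.000231, and adjusted p = 0.333 with an estimated correlation). The feedback inhibitors SPRY2 (2.19) and SPRY4 (2.14) rose, and KLF10 (-1.33), DUSP6 (-0.76) and EPHA2 (-0.59) fell. Hypoxia and glycolysis genes had 12 higher and 5 lower of 32 (12 and 5 adjusted over the list alone), with a median of 0.15 (adjusted p = 0.0319, and adjusted p = 0.3 with an estimated correlation). The collagen prolyl hydroxylase P4HA1 (1.54) and NDRG1 (1.01) rose, whereas HK1 (-1.66), TPI1, GPI, SLC2A1 and ENO1, which take up or process glucose, fell. Of 27 neuronal REST target genes, 6 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.00494, and adjusted p = 0.372 with an estimated correlation). Among them were SYT11 (0.90), KIF5A (0.54) and CELF3 (0.45, and 0.72 after quantile normalization). After quantile normalization the medians of the immediate early and hypoxia lists were 0.51 and 0.36, and after median centring that of the REST target list was 0.32. Marker lists of other cell types had positive medians in the same comparison, 0.34 (fibroblast), 0.20 (leukocyte) and 0.21 (endothelial), which camera did not call (adjusted p = 0.143, 0.144 and 0.174). Groups of unnamed probe sets, joined to the size of genes, had a median of 0.09 where dim and 0.185 where bright. The medians of the hypoxia and REST target lists did not exceed that of the bright groups.

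Several groups tied to translation, respiration and defence had more members lower than higher in MCF10A. Ribosomal protein genes had 42 lower and 0 higher of 55 (44 and 0 adjusted over the list alone), with a median of -0.46 (adjusted p = 5.67e-06, and adjusted p = 0.3 with an estimated correlation). RPL37 was at -1.95 (-1.24 with a plain median). The snoRNA host genes, whose introns carry small nucleolar RNAs, had 21 lower and 1 higher of 27 (21 and 1 adjusted over the list alone), with a median of -0.48 (adjusted p = 0.00121, and adjusted p = 0.213 with an estimated correlation). SNHG1 (-1.37), EEF1B2 (-1.06) and RPL3 (-0.88) fell, and HSPA8 rose by 0.61. The snoRNA host list shares members with the ribosomal protein list, RPL3 among them, so their calls are not independent. Of 18 microRNA host genes, 11 fell and 2 rose (12 and 2 adjusted over the list alone), with a median of -0.47 (adjusted p = 0.0195, and adjusted p = 0.32 with an estimated correlation). MEST (-2.14), SMC4 (-1.71) and CTDSPL (-1.05) fell, and CTDSP2 (0.84) and EGFL7 (0.27) rose. Oxidative phosphorylation genes had 19 lower and 2 higher of 43 (19 and 2 adjusted over the list alone), with a median of -0.29 (adjusted p = 0.0307, and adjusted p = 0.663 with an estimated correlation). NDUFA5 (-1.94) and UQCRB (-1.80, and -1.09 with no brightness minimum) fell, and COX6B1 (0.31) and UQCRC1 (0.33) rose. Of 45 interferon-stimulated genes, 21 fell and 2 rose (21 and 2 adjusted over the list alone), with a median of -0.34 (adjusted p = 0.0105, and adjusted p = 0.663 with an estimated correlation). IFI44 (-2.87), IFI44L (-2.22) and IFITM3 (-2.07) fell, and RIGI (1.44), a sensor of viral RNA, and the exonuclease ISG20 (1.57) rose. NRF2 target genes had 12 lower and 4 higher of 22 (13 and 4 adjusted over the list alone), with a median of -0.58 (adjusted p = 0.0319, and adjusted p = 0.32 with an estimated correlation). The export pumps ABCC2 (-2.70) and ABCC3 (-2.68) and the reductase AKR1C3 (-2.37) fell. SLC7A11 (1.05), TXNRD1 (0.70), FTL (0.53) and HMOX1 (0.48) rose. After quantile normalization the medians were -0.24 for ribosomal protein, -0.30 for snoRNA host, -0.11 for oxidative phosphorylation and -0.19 for interferon-stimulated genes. With another setting the call was lost for NRF2 target genes, microRNA host genes and oxidative phosphorylation genes.

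The lists of RNA processing factors were not called by camera in MCF10A. Members changed, as did 51.1% of all genes tested. The directional fry test, which does not compare a list with other genes, called the lists of SR proteins (adjusted p = 0.000689), hnRNP genes (0.00598), other splicing regulators (0.00101), the core spliceosome (0.0135) and microRNA processing (0.000224), all lower, and not the DEAD-box list (0.1). Of 25 SR proteins and SR kinases, 14 fell and 1 rose (15 and 3 adjusted over the list alone), with a median of -0.35 (-0.144 after quantile normalization and -0.209 after median centring; adjusted p = 0.136 as deposited). The kinase CLK4 (-1.32), SRSF10 (-0.90) and SRSF1 (-0.77, and -0.5 after quantile normalization) fell, and CLK3 rose by 0.62. The hnRNP genes had 14 lower and 3 higher of 29 (median -0.19 and, after quantile normalization, 0.0643; adjusted p = 0.224 as deposited). HNRNPD was at -0.94. Core spliceosome genes had 17 lower and 10 higher of 37 (18 and 11 adjusted over the list alone; median -0.14 and, after quantile normalization, 0.0895; adjusted p = 0.687 as deposited). The branch point recognition factor SF3B3 was at -1.15. Other splicing regulators had 11 lower and 5 higher of 30 (12 and 5 adjusted over the list alone; median -0.12 and, after quantile normalization, 0.0827; adjusted p = 0.483 as deposited). TIA1 was at -1.48 and SFPQ at -1.19. Of 23 genes of the microRNA processing machinery, 11 fell and 4 rose (median -0.20 and, after quantile normalization, 0.00127; adjusted p = 0.254 as deposited). TUT4 was at -1.64. The other DEAD-box helicases had 13 lower and 7 higher of 29 (median -0.15 and, after quantile normalization, 0.049; adjusted p = 0.741 as deposited). DDX20 fell by 0.97, and DDX52 (1.04) and EIF4A3 (1.02) rose. Adjusted over the list alone, the counts were the same for the hnRNP, microRNA processing and DEAD-box lists.

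In MCF7, 24 of 47 DNA replication genes and 16 of 45 interferon-stimulated genes fell after the same siRNA, and 12 of 32 junction genes and 13 of 30 stress response genes rose. With an estimated correlation none of these lists was called (adjusted p = 0.101, 0.696, 0.506 and 0.128). The largest rises were FAXDC2 at 2.07 (SE 0.088, adjusted p = 6.41e-09), TSC22D3, a glucocorticoid-induced leucine zipper protein, at 2.05 (SE 0.13, adjusted p = 2.21e-07), NUPR1 at 2.01 (SE 0.16, adjusted p = 2.08e-06) and caveolin 1, CAV1, at 2.00 (SE 0.087, adjusted p = 6.41e-09). The largest falls were ABCB6, a mitochondrial porphyrin transporter, at -2.08 (SE 0.098, adjusted p = 1.39e-08), the lipid kinase PI4K2B at -1.83 (SE 0.11, adjusted p = 1.61e-07), the co-chaperone BAG2 at -1.79 (SE 0.14) and ASF1B, a histone chaperone of dividing cells, at -1.71 (SE 0.11, adjusted p = 2.21e-07). The others were KDM7A (1.92), CD101 (1.74), AVIL (1.65), REC8 (1.60), CA8 (1.60) and TGFB2 (1.58) among the rises, and TRANK1 (-1.70), SMIM14 (-1.67), APOL3 (-1.62), UEVLD (-1.62) and PPM1G (-1.57), with DDX17 itself, among the falls. With a plain median TSC22D3 was at 1.15 and BAG2 at -1.11, and with no brightness minimum CA8 was at 1.05.

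In MCF7, 1627 genes were higher and 1505 lower (19.9% of those tested), of which 460 and 498 changed at least 1.5-fold, 75 and 96 at least 2-fold, and 3 (FAXDC2, TSC22D3 and NUPR1) and 1 (ABCB6) at least 4-fold. The groups did not overlap in 4672 genes (29.7%, where chance gives 10%). With the replicate number as a block, which reads the MCF7 arrays as paired, 2229 were higher and 2104 lower. With only the 6 MCF7 arrays in the fit, 955 were higher and 883 lower, and without the second siDDX5-17 replicate 978 were lower.

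Of 47 DNA replication and G1/S genes, 24 fell and 0 rose in MCF7 (29 and 0 adjusted over the list alone), with a median of -0.34 (adjusted p = 9.89e-12, and adjusted p = 0.101 with an estimated correlation). The replication fork helicase component CDC45 was at -1.39, the polymerase alpha subunit POLA2 at -1.31 and the origin protein ORC1 at -0.96. G2/M and mitosis genes, in contrast, had 6 higher and 1 lower of 40 (8 and 3 adjusted over the list alone), with a median of 0.15 (adjusted p = 0.0266, and adjusted p = 0.778 with an estimated correlation). This call was lost with some other settings. KIF20A (0.74) and CENPF (0.58) rose, and AURKB fell by 0.34. UBE2C was at 0.87, at 0.35 with the gene value as a mean, and at 0.22 and not called with a plain median. Interferon-stimulated genes had 16 lower and 1 higher of 45 (21 and 1 adjusted over the list alone), with a median of -0.35 (adjusted p = 1.4e-05, and adjusted p = 0.696 with an estimated correlation). RSAD2 (-1.24), OAS1 (-0.78) and IFITM1 (-0.78) fell, and HERC6 rose by 0.35. With the gene value as a mean OAS1 was at -0.31 and IFITM1 at -0.44. Of 20 cholesterol synthesis genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.12 (adjusted p = 0.0255, and adjusted p = 0.696 with an estimated correlation). The fallers were LSS (-1.04), FDPS (-0.78), MVK (-0.52), ACAT2 and MVD. Without the second siDDX5-17 replicate this list was not called.

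Of 32 epithelial junction genes, 12 rose and 1 fell in MCF7 (14 and 1 adjusted over the list alone), with a median of 0.22 (adjusted p = 0.000134, and adjusted p = 0.506 with an estimated correlation). The tight junction genes CXADR (0.91), occludin OCLN (0.87) and F11R (0.61) rose, and the desmosomal PKP3 fell by 0.49. Of 30 unfolded protein and integrated stress response genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.22 (adjusted p = 0.000147, and adjusted p = 0.128 with an estimated correlation). VLDLR (1.01) and the mitochondrial folate enzyme MTHFD2 (0.94) rose, and CRELD2 fell by 0.52. Immediate early and MAPK feedback genes had 10 higher and 1 lower of 32 (10 and 1 adjusted over the list alone), with a median of 0.20 (adjusted p = 0.00257, and adjusted p = 0.696 with an estimated correlation). DUSP6 (1.01), KLF6 (0.99) and SPRY4 (0.59) rose, and EPHA4 fell by 0.34. Of 37 estrogen receptor target genes, 8 rose and 4 fell (12 and 4 adjusted over the list alone; median 0.09, adjusted p = 0.112). STC2 (0.87, and 0.57 with a plain median) and MYBL1 (0.86) rose, and the receptor kinase RET fell by 1.16. Core spliceosome genes had 7 lower and 3 higher of 37 (7 and 3 adjusted over the list alone; median -0.04, adjusted p = 0.318). SF3B3 (-0.99) and PRPF6 (-0.75) fell.

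**Figure D2:**
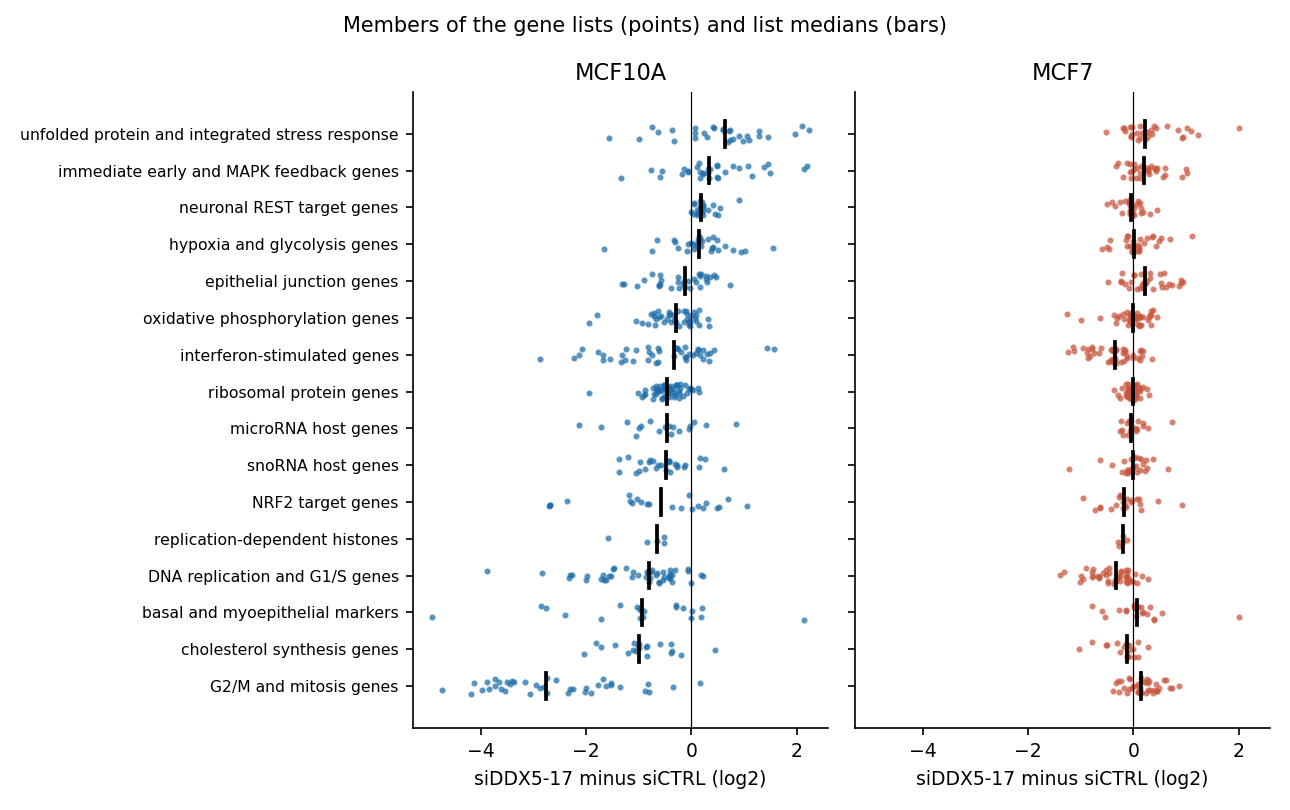
Log2 change after siDDX5-17 for the members (points) and the median (bars) of gene lists in MCF10A and MCF7. The G2/M list has a median of -2.76 in MCF10A and 0.15 in MCF7.

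The knockdown effects of the lines overlapped but differed in size and in the cell division genes. Both lines shared the rise of NUPR1 (2.23 in MCF10A and 2.01 in MCF7), AVIL (2.26 and 1.65) and KDM7A (1.51 and 1.92). They shared the fall of PI4K2B (-1.68 and -1.83), UEVLD (-2.37 and -1.62), BAG2 (-1.45 and -1.79), the importin IPO7 (-1.48 and -1.5), MAGED1 (-1.56 and -1.52) and the death ligand TNFSF10 (-2.62 and -1.46). These shared genes were singled out after their values were seen. Across genes, the log2 changes correlated with Pearson's r = 0.257 and Spearman's rho = 0.205. Of 2095 genes called in both lines, 1540 (73.5%) changed the same way. Of these, 539 were higher in both, where 326.9 would be under independence (odds ratio 2.17, Fisher's exact p = 3.62e-39). Another 1001 were lower in both, where 467 would be (odds ratio 5.29, Fisher's exact p = 2.16e-196). The remaining 461 were lower in MCF10A and higher in MCF7, and 94 the reverse.

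**Figure D3:**
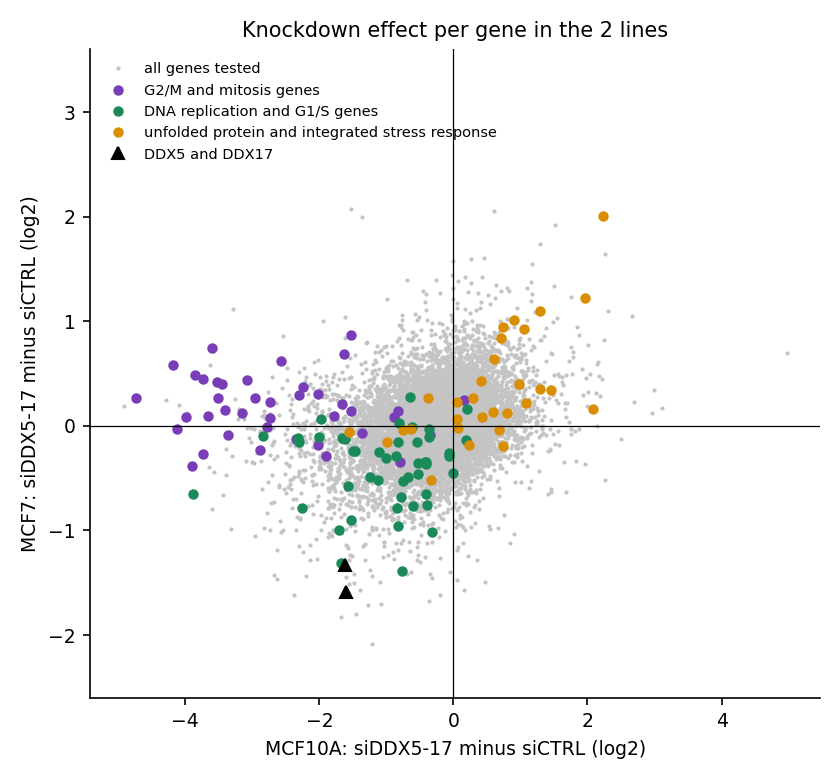
Log2 change after siDDX5-17 in MCF10A (x axis) against MCF7 (y axis), 1 point per gene, with members of selected lists and DDX5 and DDX17 in color. Pearson's r across genes was 0.257, and the G2/M genes lie far to the left near 0 on the y axis.

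The difference between the effects (MCF7 minus MCF10A) was tested directly and was past the threshold in 5921 genes, 4030 with a higher and 1891 with a lower value in MCF7. The share of higher values was 68.1% as deposited, 45.3% after quantile normalization (3262 higher, 3946 lower) and 49.7% after median centring (3362 and 3399). The scalings moved the median difference to -0.132 and -0.113. The largest positive differences were KRT15 at 5.11 (adjusted p = 1.35e-11), TOP2A at 5.00 (adjusted p = 1.64e-09), CENPF at 4.76 (adjusted p = 1.35e-11), PCDHB14 at 4.54, the epithelial transcription factor EHF at 4.40 and the mitotic kinesin KIF20A at 4.35. The largest negative ones were CRYAB at -4.27 (adjusted p = 6.46e-09), ARG2 at -2.94, OLAH at -2.84, MORN4 at -2.78, FCRL6 at -2.65 and RDH10 at -2.62.

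Of the lists, G2/M and mitosis genes differed the most, with 38 of 40 members higher in MCF7 relative to MCF10A and 0 lower (median difference 2.89, adjusted p = 7.1e-30, and adjusted p = 0.115 with an estimated correlation). Positive differences were also called for basal markers (14 higher and 1 lower of 20; median 0.97, adjusted p = 4.68e-05, and adjusted p = 0.115 with an estimated correlation) and cholesterol synthesis genes (16 and 1 of 20; median 0.89, adjusted p = 4.68e-05, and adjusted p = 0.205 with an estimated correlation). Ribosomal protein genes (30 and 0 of 55; median 0.43, adjusted p = 4.68e-05, and adjusted p = 0.435 with an estimated correlation) and DNA replication genes (23 and 3 of 47; median 0.39, adjusted p = 0.00353, and adjusted p = 0.435 with an estimated correlation) had the same direction. So did snoRNA host genes (14 and 1 of 27; median 0.43, adjusted p = 0.00993, and adjusted p = 0.435 with an estimated correlation), microRNA host genes (12 and 1 of 18; median 0.60, adjusted p = 0.0172, and adjusted p = 0.435 with an estimated correlation) and junction genes (13 and 2 of 32; median 0.38, adjusted p = 0.0325, and adjusted p = 0.542 with an estimated correlation). Negative differences were called for neuronal REST target genes (0 higher and 6 lower of 27; median -0.27, adjusted p = 0.00483, and adjusted p = 0.51 with an estimated correlation) and immediate early genes (4 and 9 of 32; median -0.20, adjusted p = 0.0235, and adjusted p = 0.565 with an estimated correlation). After quantile normalization the medians were 0.17 for ribosomal protein, 0.21 for snoRNA host, 0.17 for junction and -0.43 for immediate early genes. Adjusted over the list alone, the counts were the same for these lists except for ribosomal protein genes (37 and 0), DNA replication genes (24 and 4), snoRNA host genes (18 and 1) and junction genes (14 and 2). The calls for junction, immediate early, microRNA host and REST target genes were lost with some other settings.

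At the exon level, many probe sets changed relative to their gene in MCF10A, and far fewer in MCF7. RAC1, a small GTPase of the cytoskeleton, had the same probe set, 2989056, higher in both lines: its splicing index rose by 1.94 in MCF10A (SE 0.18, adjusted p = 1.98e-05) and by 1.49 in MCF7 (SE 0.18, adjusted p = 0.00183), a difference between the lines of -0.44 (adjusted p = 0.399). Of 26 probe sets annotated to RAC1, 3 were called in MCF10A and 1 in MCF7. They fall in separate runs of identifiers (2768033 to 2768038, 2780942, and 2989053 to 2989081), and it was not checked that all lie in RAC1. Probe set 2768035, called in MCF10A, is outside the run of 2989056. In MACROH2A1, a histone variant gene, probe set 2876485 rose by 1.45 in MCF10A (SE 0.14, adjusted p = 2.61e-05), and a different one, 2876501, rose by 1.22 in MCF7 (SE 0.15, adjusted p = 0.00179). The latter was at -0.08 in MCF10A (adjusted p = 0.781), a difference between the lines of 1.31 (adjusted p = 0.00321). The MCF7 call was lost with only the 6 MCF7 arrays in the fit. On simulated data, false calls made up 51.1% of the MCF7 probe set calls of the 12-array fit used here. Fewer probe sets were changed there than were called on the real arrays, so this share need not hold for the real calls. GSK3B probe set 2691039 rose in MCF7 by 1.5 (SE 0.18, adjusted p = 0.0016) and measured 1.17 in MCF10A. In CD44, whose variable exons are spliced differently across epithelial states, probe set 3326687 changed by -1.78 in MCF10A (SE 0.14, adjusted p = 5.65e-06).

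**Figure D4:**
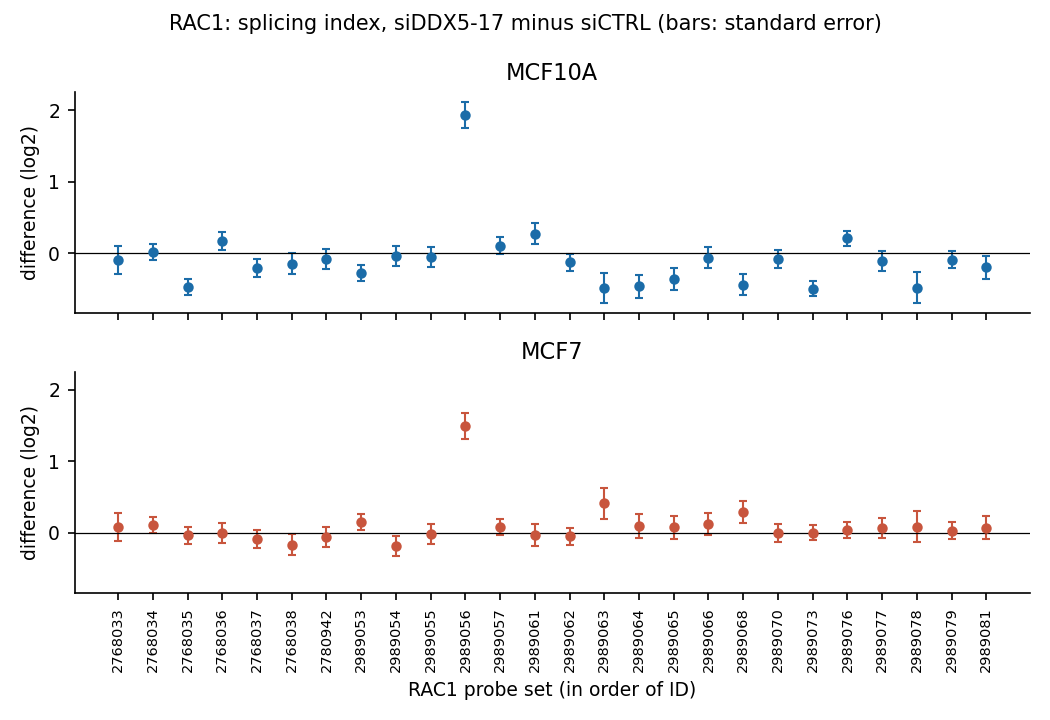
Splicing index difference (log2, siDDX5-17 minus siCTRL) of each of 26 probe sets annotated to RAC1, in identifier order, in MCF10A and MCF7, with bars of 1 SE. Probe set 2989056 stands at 1.94 in MCF10A and 1.49 in MCF7.

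In MCF10A, 34006 of 232976 probe sets (14.6%) were called, in 9143 of 14446 genes. Of these, 16979 were higher and 17027 lower, and 5331 and 4869 changed at least 2-fold. The largest were in TMEM107 (3744232, 4.87, SE 0.13, adjusted p = 4.47e-09), KRT15 (3757102, 4.51, SE 0.21, adjusted p = 2.05e-07), DLGAP5 (3565675, 4.35), CCNB1 (2813417, 4.34), STMN1 (2402467, -4.32, SE 0.48, adjusted p = 7.6e-05) and CENPE (2780255, 4.27). The genes themselves changed by -4.92 (KRT15), -3.73 (DLGAP5), -3.98 (CCNB1), -3.85 (CENPE), -0.40 (TMEM107) and -0.21 (STMN1). In KRT15, DLGAP5, CCNB1 and CENPE the index rose about as far as the gene fell, so the probe set itself moved far less. These rises cannot be told apart from probe sets that did not follow their gene. With siCTRL in MCF10A these probe sets were at 6.53, 10.68, 5.94 and 7.58, and that of CCNB1 was dimmer than the brightness minimum. Of the 50 listed splicing events, 47 genes were tested and 41 had a called probe set, with 201 of 1312 probe sets called, 82 higher and 119 lower (211 adjusted over the list alone). That share was 15.3%, against 14.6% in the other genes. Besides RAC1, MACROH2A1 and CD44, these included HNRNPDL (2775568, -1.72), ENAH (2458376, -1.52), SYNE2 (3539772, -1.41), CASP8 (2522756, -1.28) and BCL2L1 (3902532, -1.17). The called share was 44.5% in genes that fell at least 4-fold and 5.9% in genes whose value was higher by less than 1.5-fold, and 12350 probe sets were called when only genes changed under 1.5-fold were tested. With the brightness minimum at the upper quartile 20162 were called.

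In MCF7, 2668 of 252430 probe sets (1.06%) were called, in 1624 of 14741 genes. This count was 1236 and 1377 without the second and the third siDDX5-17 replicate, 1456 and 1208 without the second and the third siCTRL replicate, and 4034 with diffSplice. Of the 2668, 1468 were higher and 1200 lower, and 715 and 457 changed at least 2-fold. The largest were in OAS1 (3432464, 3.91, SE 0.24, adjusted p = 3.81e-05), MRPL37 (2337030, 3.83, SE 0.21, adjusted p = 1.7e-05; 1.85 in MCF10A), CAPN10 (2535910, 3.32, SE 0.66, adjusted p = 0.0317; 2.19 in MCF10A), DBNL (2999748, 2.86), CST3 (3901302, 2.76) and PHKG2 (3656554, 2.76, SE 0.29, adjusted p = 0.00103; 2.93 in MCF10A). With siCTRL in MCF7 all of these probe sets were dimmer than the brightness minimum. Their log2 values there were 4.55 (OAS1), 5.82 (MRPL37), 4.62 (CAPN10), 5.36 (DBNL), 5.27 (CST3) and 5.05 (PHKG2). These differences therefore rest on dim control values. Of the listed splicing events, 48 genes were tested and 14 had a called probe set, with 23 of 1411 probe sets called, 17 higher and 6 lower (28 adjusted over the list alone). That share was 1.63%, against 1.05% in the other genes. They included CEACAM1 (3863691, 1.31), FN1 (2598304, -1.16), TJP1 (3615612, 1.14), EPB41 (2327684, 0.95) and SRSF3 (2905128, 0.82). With only the 6 MCF7 arrays in the fit, 268 probe sets were called, and those in CAPN10, MACROH2A1, TJP1, EPB41 and SRSF3 were not. On simulated data, which need not match the real share of changed probe sets, false calls made up 2.5% of the calls of this 6-array fit.

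The probe sets called in both lines moved mostly the same way. Singled out after their values were seen, these included the kinase CLK3 (3601807, 3.18 in MCF10A and 2.45 in MCF7), the splicing coactivator SRRM2 (3645300, -2.61 and -2.27), REEP5 (2871179, -2.21 and -1.87), ODC1 (2.53 and 1.97), CTSD (3.15 and 1.87) and SMPD4 (-1.96 and -1.90). Of 1284 probe sets called in both, 1167 (90.9%), in 784 genes, had the same direction. Of these, 623 were higher in both, where 99.6 would be under independence (odds ratio 11.1), and 544 lower in both, where 80.1 would be (odds ratio 12.8). With only the arrays of each line in the fit, 158 were called in both and 148 had the same direction. Across probe sets, the differences correlated at r = 0.226 and rho = 0.155. The difference between the lines was past the threshold for 10942 of 228040 probe sets (4.8%), 5071 higher and 5871 lower in MCF7. This count was 17200 with the replicate number as a block. It was 6808, 7174 and 7211 without the first, the second and the third MCF10A siCTRL replicate, and 6976 without the third MCF7 siCTRL replicate.

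With control siRNA, luminal markers were higher and basal markers lower in MCF7 than in MCF10A. Of 15 luminal markers, 14 were higher in MCF7 and 0 lower, with a median of 3.57 (adjusted p = 0.00136, and adjusted p = 0.279 with an estimated correlation). They included PRLR (3.97), GATA3 (3.77), KRT8 (3.57), TSPAN13 (3.54) and KRT18 (3.50). Of 20 basal markers, 17 were lower and 0 higher, with a median of -1.68 (adjusted p = 9.19e-34, and adjusted p = 0.000382 with an estimated correlation). They included KRT15 (-4.92), DSG3 (-4.90), KRT5 (-4.63), EGFR (-3.60) and CAV1 (-2.97). The largest values in MCF7 were the interferon-induced IFIT1 (7.75), OAS2 (7.49), IFIT3 (6.42), IFIT2 (6.32) and RSAD2 (6.16), the estrogen-induced TFF1 (7.20), and CEP15 (7.42), SLC6A14 (6.99), SPTSSB (6.42) and GFRA1 (6.37). The lowest were complement C3 (-5.95), DSC3 (-5.70), ROS1 (-5.50), PNLIPRP3 (-5.46), SELENOP (-5.21), PTPRM (-4.94), ANPEP (-4.78) and TUT4 (-4.66), with KRT15 and DSG3. With the brightness minimum at the upper quartile TUT4 was at -2.29.

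As deposited, 13088 genes were higher and 1315 lower in MCF7 (91.5% of those tested), and the groups did not overlap in 14423 genes (91.7%, where chance gives 10%). The whole distribution was shifted, with a median difference of 0.911 (1.88-fold). Relative to that median, 7867 called genes were higher and 6536 lower, of which 1612 and 1623 differed at least 2-fold. After quantile normalization 5395 were higher and 4691 lower (53.5% higher, median 0.0541), and after median centring 5385 and 4600 (53.9%, median 0.0363). Relative to the median, IFIT1 was at 6.84, TFF1 at 6.29, KRT8 at 2.66, GATA3 at 2.86, KRT5 at -5.55 and C3 at -6.86. DDX5 was higher in MCF7 by 1.65 (0.74 relative to the median, 0.53 after quantile normalization and 0.77 after median centring). DDX17 was at 0.30 as deposited (adjusted p = 0.00855) but at -0.83 after quantile normalization and -0.58 after median centring.

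In this comparison the counts adjusted over the list alone were the same as those over all genes. Among the other lists, mesenchymal genes were lower in MCF7 (14 lower and 10 higher of 28; median -0.57, adjusted p = 1.39e-15, and adjusted p = 0.0143 with an estimated correlation). Interferon-stimulated genes were higher (44 and 1 lower of 45; median 3.78, adjusted p = 1.56e-05, and adjusted p = 0.524 with an estimated correlation), as were DNA replication genes (47 of 47; median 2.36, adjusted p = 8.1e-06, and adjusted p = 0.161 with an estimated correlation) and estrogen receptor target genes (36 and 1 lower of 37; median 1.74, adjusted p = 0.00359, and adjusted p = 0.44 with an estimated correlation). Ribosome biogenesis (45 of 45; median 1.8, adjusted p = 0.000222, and adjusted p = 0.435 with an estimated correlation), ribosomal protein (53 of 55; median 1.38, adjusted p = 0.00831, and adjusted p = 0.528 with an estimated correlation) and core spliceosome genes (34 of 37; median 1.46, adjusted p = 0.0161, and adjusted p = 0.528 with an estimated correlation) were higher too. The same held for hnRNP genes (28 and 1 lower of 29; median 1.58, adjusted p = 0.0315, and adjusted p = 0.615 with an estimated correlation), DEAD-box helicases (27 and 1 lower of 29; median 1.76, adjusted p = 0.0335, and adjusted p = 0.528 with an estimated correlation) and G2/M genes (37 and 1 lower of 40; median 1.61, adjusted p = 0.0397, and adjusted p = 0.65 with an estimated correlation). After quantile normalization the medians were -2.65 (basal), -1.39 (mesenchymal), 1.4 (DNA replication), 0.823 (estrogen receptor target), 0.819 (ribosome biogenesis), 0.234 (ribosomal protein), 0.329 (core spliceosome), 0.433 (hnRNP), 0.829 (DEAD-box) and 0.59 (G2/M). The ribosomal protein call was lost with quantile normalization, the hnRNP, DEAD-box and G2/M calls with the gene value as a mean, and the G2/M call also with the brightness minimum at the upper quartile. For 3 of the called lists the sign of the median and the direction of the test, which compares a list with all other genes, differed. Extracellular matrix genes and integrins had a median of 0.52 (-0.41 after quantile normalization) and a mean of -0.11, and the test gave lower (adjusted p = 2.32e-07, and adjusted p = 0.00591 with an estimated correlation). The p53 target genes had a median of 0.06 (-0.81 after quantile normalization), and the test gave lower (adjusted p = 9.72e-07, and adjusted p = 0.149 with an estimated correlation). NF-kB and inflammatory genes had a median of 0.64 (-0.19 after quantile normalization), and the test gave lower (adjusted p = 0.00359, and adjusted p = 0.217 with an estimated correlation).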

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

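Of the tests in this part, those of the unnamed probe sets, of the replicate spread, of an array difference for the probe set counts and for the G2/M genes, of partial following in genes changed under 1.5-fold, and of single arrays were chosen after the result was seen.

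The knockdown effect differed between the lines in 5921 genes and 10942 probe sets, by a test of the difference itself. The same test gave median differences (MCF7 minus MCF10A) of 2.89 for G2/M and mitosis genes, 0.974 for basal markers, 0.885 for cholesterol synthesis genes, 0.603 for microRNA host genes, 0.434 for ribosomal protein genes, 0.429 for snoRNA host genes, 0.389 for DNA replication genes, 0.376 for epithelial junction genes, -0.203 for immediate early genes and -0.266 for neuronal REST target genes. With an estimated correlation 0 of these 10 lists were called (adjusted p from 0.115 to 0.565), and the calls for junction, immediate early, microRNA host and REST target genes were lost with some other settings. For single genes it gave 5.11 (KRT15), 5.00 (TOP2A), 4.76 (CENPF), 4.54 (PCDHB14), 4.40 (EHF), 4.35 (KIF20A), -4.27 (CRYAB), -2.94 (ARG2), -2.84 (OLAH), -2.78 (MORN4), -2.65 (FCRL6) and -2.62 (RDH10).

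Probe sets with no gene symbol, which no comparison of the report used, also changed: 64352 of 1038473 (6.2%; 28634 higher and 35718 lower) in MCF10A and 1744 (0.168%; 1454 higher and 290 lower) in MCF7.

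More genes changed in MCF10A than in MCF7 (8043 against 3132). A smaller spread between the MCF10A replicates is argued against as a cause of these counts, since the fit used 1 spread per gene for both lines. Without any test, 1624 genes changed at least 2-fold in MCF10A and 171 in MCF7, a ratio of 9.5. A difference between the arrays of the MCF10A groups that reaches probe sets of every kind cannot be told apart from an effect of the siRNA. When dim unnamed probe sets were joined into groups of the size of genes, 5.43% of these groups were called with a 1.5-fold change in MCF10A and 0.019% in MCF7, against 23.7% of the genes in MCF10A. For groups of bright unnamed probe sets these shares were 7.22% and 0.657%. Without the 1.5-fold minimum, 37.7% of the bright groups were called in MCF10A and 1.3% in MCF7. The shares of genes were 51.1% and 19.9%. Unnamed probe sets, dim or bright, may hold true transcripts. A difference between the cell lines stays open as well and was not tested apart from an array difference.

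Probe sets were also called more often in MCF10A (34006) than in MCF7 (2668). Probe sets that follow their gene's change only in part cannot be the whole cause, since in genes changed under 1.5-fold 9.6% were called in MCF10A and 0.746% in MCF7, a ratio of 12.9. In MCF10A genes that fell at least 2-fold they may account for some of the calls: with each gene's probe sets in 3 classes of brightness, the dimmest class was called higher in 33.4% and the brightest in 14.3%, a ratio of 2.34. An array difference between the MCF10A groups cannot be told apart, since 4.79% of the dim unnamed probe sets were called in MCF10A and 0.0801% in MCF7. Of the bright unnamed probe sets, 8.2% and 0.293% were called. A difference in splicing between the cell lines stays open.

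G2/M and mitosis genes fell as a list in MCF10A and not in MCF7, with a median difference of 2.89 (adjusted p = 0.115 with an estimated correlation). Under quantile normalization and median centring the median was at least 2.77. These scalings moved the median difference of all genes only from 0.00119 to -0.132 and -0.113, so they could hardly have removed the list's difference. They show only that it outlasts a rescaling of the deposited values, which were already normalized. As a cause, 1 array is argued against by a median of at least 2.85 with each array left out. In MCF10A, 0.155% of the groups of dim and 0.149% of the groups of bright unnamed probe sets fell at least 4-fold, against 70% of the G2/M genes (28 of 40). A fall of that size common to probe sets of every kind was therefore not seen. The groups join probe sets in identifier order, which need not move together, so an array difference in part of the probe sets cannot be told apart by this test. The bounds first set for this last test did not decide and were replaced after the value was seen. A difference between the lines in how they respond stays open as a hypothesis, as does an effect of the siRNA on other transcripts in 1 of the lines.

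For each comparison of 3 against 3 arrays there are 10 splits, which cannot give a share under 0.05, and 1 of the 10, the real one, gave a count as large. The real count and the highest other were 8043 and 0 for MCF10A genes, 3132 and 1 for MCF7 genes, 14403 and 0 for the control comparison, 34006 and 0 for MCF10A probe sets, 2668 and 0 for MCF7 probe sets, 64352 and 1 for unnamed MCF10A probe sets, and 1744 and 0 for unnamed MCF7 probe sets. In MCF7, if the replicate numbers are read as pairs, 3 other splits part all pairs, and the highest count among them was 0 for genes and for probe sets.

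For the difference between the lines, 100 splits within the lines were drawn. As many genes (5921 or more) came from 3 of the 100 and as many probe sets (10942 or more) from 7, the real one included, and the highest others gave 6788 and 23954. These shares decide nothing about the difference. A split within the lines also removes the siRNA effect of each line, so that an effect in MCF10A alone would pass, and the bound set before did not allow for this. The other splits with as many (2 for genes and 6 for probe sets) were all among the 8 that kept the MCF10A siRNA groups, and those that did not keep them gave at most 61 genes and 17 probe sets.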

How the results depend on the processing

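Of 29 settings, 2 were chosen after seeing the data: leaving out both first MCF7 arrays (MCF10A 4344 higher and 5452 lower genes, MCF7 1812 and 1682) and a brightness minimum per line (3237 and 5014, 1644 and 1523). Not every setting gave a value for every named result: each named gene and probe set had 21 to 23, since the upper quartile minimum left some genes and 14 of the 28 named probe sets out, the block gave no control comparison, the 6-array fit no difference between the lines, the minimum per line left out a probe set, and centring gave no exon value. In the settings run for them, the named genes kept their direction and their side of the threshold in 121 of 128 cases in MCF10A, 94 of 110 in MCF7, 13 of 14 for the difference between the lines and 29 of 30 in the control comparison, and the named probe sets in 14 of 14 (MCF10A) and 9 of 14 (MCF7). List calls from camera at the preset correlation were kept in all other settings that use this test for 12 of 15, 5 of 7, 6 of 10 and 11 of 15 lists. With an estimated correlation, 0, 0, 0 and 3 were called. The signal over background limits dim genes: 18207 genes could be tested with no brightness minimum and 12279 with the minimum at the upper quartile.

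With quantile normalization, 6021 genes were higher in MCF10A, 3946 were lower in the difference between the lines, and 5395 and 4691 were higher and lower in the control comparison. With median centring these counts were 5924, 3399, 5385 and 4600; centring cancels in the splicing index and gave no exon value. DDX17 in the control comparison reversed to -0.83 and -0.58. The scalings moved the median of all genes from 0.0192 to 0.147 and 0.156 in MCF10A, from 0.00119 to -0.132 and -0.113 in the difference, and from 0.911 to 0.0541 and 0.0363 in the control comparison; the cause was not tested.

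With the replicate number as a block, which reads the MCF7 arrays as paired, 2229 genes were higher and 2104 lower in MCF7, 4137 and 5355 in MCF10A, and 4660 and 2796 in the difference between the lines; probe sets called were 3723, 43876 and 17200. Only the last left 1.5 times its count, and the NRF2 list was no longer called in MCF10A; the cause was not tested. The control comparison cannot be estimated with this block. With only the 6 arrays compared, 955 and 883 genes and 268 probe sets were called in MCF7. In MCF10A, with as few arrays, the counts were 4119 and 5363 genes and 41668 probe sets, so that the loss of degrees of freedom alone does not account for the fall in MCF7. The median SD between replicates was larger in MCF7 (0.136 and 0.132) than in MCF10A (0.0859 and 0.0964), and the cause was not tested further.

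With the brightness minimum at the upper quartile, 20162 probe sets were called in MCF10A and 6683 in the difference between the lines, with fewer probe sets tested. A 1.5-fold minimum left 766 and 2964 genes in MCF10A and 460 and 498 in MCF7 by construction. Restricted to genes changed under 1.5-fold, 12350 and 1321 probe sets were called. The diffSplice test called 4034 in MCF7, and the cause was not tested. DCN in MCF7 reversed to 0.21 with no brightness minimum, 0.05 with the minimum at the upper quartile and 0.07 with a plain median, and the cause was not tested.

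In MCF10A, MCF7, the difference and the control comparison, camera called 15, 7, 10 and 15 of 38 lists, the directional fry test 31, 10, 25 and 37, and the mixed fry test 38, 31, 38 and 38. The directional test did not call the G2/M, interferon-stimulated and immediate early lists in MCF7 and the immediate early list in the difference, which camera called. This test, which asks whether a list moves from 0 where camera compares it with other genes, gave the opposite direction for estrogen receptor targets in the difference between the lines (median -0.0852). In the control comparison, with its median shift of 0.911, it did so for junction (0.985), SR protein (0.832), microRNA processing (1.02), microRNA host (1.12), p53 target (0.0594), NF-kB (0.639), cholesterol synthesis (0.77), Notch (0.963), immediate early (0.852), epidermal (0.774), leukocyte (0.532) and endothelial (0.759) lists.

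With each array left out in turn, counts ranged from 2372 to 3700 (higher) and 4438 to 5151 (lower) genes in MCF10A, 1204 to 1708 and 978 to 1575 in MCF7, 3580 to 4263 and 1426 to 2523 in the difference between the lines, and 12880 to 13158 and 1205 to 1345 in the control comparison. Pearson's r ranged from 0.214 to 0.27 (jackknife SE 0.0483). Probe sets ranged from 23555 to 39268 in MCF10A, 1208 to 3084 in MCF7 and 6808 to 13766 in the difference. The lowest MCF7 gene count, 978, came without the second siDDX5-17 replicate. MCF7 probe sets fell to 1236 and 1377 without the second and the third siDDX5-17 replicate, and to 1456 and 1208 without the second and the third siCTRL replicate. Probe sets in the difference fell to 6808, 7174 and 7211 without the first, the second and the third MCF10A siCTRL replicate, and to 6976 without the third MCF7 siCTRL replicate; fewer arrays were left in each fit. Where this left 2 arrays in a group, the pooled spread was used.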

Other observations

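In MCF10A, further lists were not called by camera. Members of them changed, as did 51.1% of all genes tested, so the counts alone do not set these lists apart. Of 41 extracellular matrix genes and integrins, 19 fell and 11 rose (median -0.05, adjusted p = 0.168), with the laminin LAMB1 at -2.82, ITGA6 at -2.01 and HSPG2 at -1.86. Of 32 epithelial junction genes, 11 fell and 6 rose (median -0.13, adjusted p = 0.687), with E-cadherin CDH1 at -1.31, CLDN1 at -1.28 and the splicing regulator ESRP1 at -1.03. Mesenchymal genes had 9 lower and 7 higher of 28 (median -0.05, adjusted p = 0.687), with SNAI2 at -3.02, LOX at -2.68 and AXL at -2.20 (-0.68 with the minimum at the upper quartile). TGF-beta and SMAD target genes had 11 higher and 5 lower of 27 (median 0.17, adjusted p = 0.144), though ITGB6 (-2.62, and -1.67 with the brightness minimum at the upper quartile), TGFB1 (-1.51) and TGFBR2 (-0.95) fell. Of 35 p53 target genes, 11 rose and 9 fell (median -0.000244, adjusted p = 0.224): the cell cycle inhibitor CDKN1A (1.42) and PLK3 (1.16) rose and CYFIP2 fell by 1.84. Estrogen receptor target genes had 12 higher and 10 lower of 37 (median 0.12, adjusted p = 0.375), with MYBL1 at -2.55, GREB1 at -2.46 and SLC7A5 at -1.83. Luminal markers had 3 higher and 5 lower of 15 (median 0.02, adjusted p = 0.779), with EPCAM at -2.40, PRLR at -0.50 and TBX3 at 0.48. PRLR was at -0.16 and not called after quantile normalization, TBX3 at 0.28 and not called with the minimum at the upper quartile, and EPCAM at -1.41 with a plain median.

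The remaining MCF10A lists were ribosome biogenesis (20 lower and 7 higher of 45; median -0.19, adjusted p = 0.16), NF-kB and inflammatory genes (7 and 0 of 22; -0.19, adjusted p = 0.679), the Notch pathway (8 and 1 of 21; 0.03, adjusted p = 0.687), Wnt targets (4 and 5 of 20; 0.03, adjusted p = 0.761), epidermal differentiation (5 and 6 of 26; 0.06, adjusted p = 0.286), steroid receptors and coregulators (8 and 4 of 22; -0.03, adjusted p = 0.779) and apoptosis regulators (10 and 4 of 31; -0.01, adjusted p = 0.779). Markers of other cell types moved in both directions. Fibroblast markers had 6 higher and 2 lower of 11 (median 0.34, adjusted p = 0.143), with MFAP5 at 1.45, FBLN1 at -1.13 and PDPN at -1.97. With the brightness minimum at the upper quartile PDPN was at -0.22 and not called. Leukocyte markers had 2 higher and 1 lower of 9 (0.20, adjusted p = 0.144), namely LCP1 (1.16), PTPRC (0.46) and CD14 (-0.43). With no brightness minimum PTPRC was at 0.1 and CD14 at -0.16, and neither was called. Endothelial markers had 3 higher and 2 lower of 11 (0.21, adjusted p = 0.174), with TEK at 1.44, KDR at -0.96 and ENG at -0.79. With the minimum at the upper quartile KDR was at -0.52, and ENG was at -0.23 and not called. The median changed sign with quantile normalization for junction, mesenchymal, p53 target, NF-kB, matrix, steroid receptor and apoptosis lists. Mean and median differed in sign for estrogen receptor target (mean -0.07), luminal (-0.13), p53 target (0.14), Wnt (-0.05) and Notch (-0.21) lists. The test direction followed the mean for p53 target and Notch lists and the median for the others. Adjusted over the list alone, the counts differed for mesenchymal (10 lower and 7 higher) and ribosome biogenesis genes (20 and 8). The directional fry test, which does not compare a list with other genes, called the matrix list (adjusted p = 3.62e-08), the Notch (0.000129), mesenchymal (0.000158), steroid receptor (0.000778), ribosome biogenesis (0.00163), apoptosis (0.00306), NF-kB (0.0092) and junction (0.0161) lists, and the endothelial (0.0022), fibroblast (0.0365) and leukocyte (0.0405) markers.

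In MCF7, single members of lists that camera did not call changed as well, as did 19.9% of all genes tested. Among mesenchymal genes, 5 rose and 1 fell of 28 (median 0.00339, adjusted p = 0.257), with smooth muscle actin ACTA2 at 1.44, TGFBI at 1.28 and CALD1 at 1.04. Basal markers had 4 higher and 2 lower of 20 (0.07, adjusted p = 0.318), with the caveolins CAV1 (2.00) and CAV2 (0.55) higher and CDH3 (-0.79) lower. CAV2 was at 0.4 and not called with a plain median. TGF-beta and SMAD target genes had 7 higher and 3 lower of 27 (0.06, adjusted p = 0.311), with TGFB2 at 1.58 and TGFB1 at -1.24. Ribosome biogenesis genes had 8 lower and 1 higher of 45 (-0.03, adjusted p = 0.142), with nucleolin NCL at -1.23, nucleophosmin NPM1 at -0.78 and NAT10 at -0.77.

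Counts higher and lower in the other MCF7 lists were 4 and 5 of 29 DEAD-box helicases (median -0.05, adjusted p = 0.449), 2 and 2 of 15 luminal markers (0.09, adjusted p = 0.413), 3 and 4 of 29 hnRNP genes (0.06, adjusted p = 0.732), 4 and 3 of 25 SR proteins and kinases (0.05, adjusted p = 0.492), and 5 and 2 of 30 other splicing regulators (0.02, adjusted p = 0.449). They were 5 and 2 of 23 microRNA processing genes (0.14, adjusted p = 0.148), 7 and 5 of 35 p53 targets (0.06, adjusted p = 0.319), 7 and 4 of 32 hypoxia genes (0.02, adjusted p = 0.318), 2 and 6 of 22 NRF2 targets (-0.17, adjusted p = 0.112), and 6 and 5 of 31 apoptosis regulators (0.09, adjusted p = 0.492). They were 4 and 1 of 22 steroid receptors and coregulators (0.11, adjusted p = 0.13), 4 and 3 of 41 matrix genes (-0.07, adjusted p = 0.713), 2 and 5 of 43 oxidative phosphorylation genes (-0.00838, adjusted p = 0.95), 2 and 3 of 27 snoRNA hosts (0.0025, adjusted p = 0.862), and 1 and 2 of 27 REST targets (-0.05, adjusted p = 0.713). Medians were -0.08 for NF-kB genes (adjusted p = 0.533), -0.05 for Wnt targets (adjusted p = 0.872), -0.000344 for the Notch pathway (adjusted p = 0.862), -0.05 for microRNA hosts (adjusted p = 0.907), -0.01 for ribosomal protein genes (adjusted p = 0.81), 0.04 for epidermal genes (adjusted p = 0.318) and -0.20 for the 5 histones (adjusted p = 0.238). For markers of other cell types they were -0.10 for fibroblasts (adjusted p = 0.461), -0.02 for leukocytes (adjusted p = 0.872) and -0.03 for endothelium (adjusted p = 0.872). The fibroblast marker DCN was at -0.32 and reversed with some settings. Mean and median differed in sign for microRNA host (mean 0.01), Wnt (0.02), Notch (0.03) and snoRNA host (-0.03) lists, whose test followed the mean. The median changed sign with quantile normalization for other splicing regulators and the Notch, snoRNA host and leukocyte lists, and with median centring for the Notch, ribosomal protein, oxidative phosphorylation and leukocyte lists. Adjusted over the list alone, the counts higher and lower differed for basal (6 and 4), microRNA processing (6 and 2), p53 target (8 and 5) and apoptosis genes (8 and 5). They also differed for the Notch pathway (1 and 0 over all genes, RBPJ; 0 and 0 over the list), ribosomal protein genes (1 and 0, RPL28; 0 and 0), fibroblast markers (0 and 1, DCN; 0 and 0) and leukocyte markers (0 and 1, LCP1; 1 and 1). The calls over all genes for RBPJ, RPL28, DCN and LCP1 were lost with some other settings. The directional fry test called basal markers (adjusted p = 0.0061), NRF2 targets (0.0153), steroid receptors (0.0153), hypoxia genes (0.0225), TGF-beta targets (0.0253) and mesenchymal genes (0.0499).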
